A study of Homo sapiens with 15 samples.

How the data were processed

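Gene expression was measured on 15 single-colour microarrays of ASC52 cells, 5 arrays in each of 3 groups named MSC, MA and DED, which were taken from the sample titles. The authors deposited log2 intensity values, 1 table for all arrays, summarised per probe set with RMA in Transcriptome Analysis Console, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises probes on the log2 scale, so that a shift shared by all genes of a group cannot be read from the values. Software versions, the RMA variant and the genome build behind the probe sets are not given in the sources used here. The deposited values have 2 decimals and run from 2.61 to 18.35.

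The table holds 24351 probe sets, of which 17709 carried 1 gene symbol in the platform annotation, 0 carried several, 3739 transcript probe sets carried none and 2903 were controls. All 17709 Entrez identifiers were matched to the reference gene table and 0 symbols differed. For the 20 genes with several probe sets the probe set with the highest mean over all arrays was kept, which left 17687 genes. No filter on dim probe sets was applied. The 612 negative control probe sets had a median of 4.80 and a 95th percentile of 8.31, and a difference whose lower group lies under that median depends on background, so it is given as a log2 difference and not as a fold.

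Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 15 arrays sharing the estimate of the spread, no covariates, no intensity trend). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 17687 genes, and a gene passed the test at an adjusted p under 0.05. Counts are also given for genes that passed with a fold of 2 or more. Values are means ± SD over 5 arrays, and the SE is that of the moderated log2 difference. Moderation draws the spread of each gene towards that of all genes. The precision is limited by the number of arrays.

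The fixed lists held 587 genes, of which 537 were measured, in 29 lists. Each list was tested per comparison with camera on the same fit with an inter-gene correlation of 0.01, and the 87 p-values were adjusted together by Benjamini-Hochberg. Camera compares a list with all other genes, so a list can pass it on a small median. Each list is also given as its number of members past the test, over all genes and adjusted over the list alone. Camera with the correlation estimated per list and fry, which tests whether a list moves one way on balance, were run beside it. A further 9 lists were written after the largest changes had been seen and are reported apart from the others.

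Named genes were chosen by a rule with 3 parts. Per comparison it took the 10 largest rises and the 10 largest falls among genes past the test whose groups of arrays do not overlap. Per list and comparison it took up to 2 members with the largest rise and up to 2 with the largest fall among those past the test, of which fewer are named. In every comparison it took 20 genes whatever their test, among them PPARG, ADIPOQ, COL1A1, IL6 and MKI67. The overlap of both steps was compared with independent lists and with the MA arrays split into 2 and 3 in all ways, and the correlation of both steps with 100 simulations of unchanged groups that share the MA arrays.

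The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were quantile normalization, a shift of each array to 1 median, dim genes left out (mean under the 25th percentile), all probe sets tested singly, an intensity trend with robust fit, array weights, fits of only the groups compared, the replicate number as a block, and each array left out in turn. Leaving out DED arrays 1 and 3 together, and leaving out each array in turn for the list tests, were added later. Random splits of the 10 arrays of each comparison numbered 100. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

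The gene test was tested on simulated data with 200 of 17687 genes changed by known folds. In the simulation of DED against MA it recovered 64% of genes changed 1.5-fold and 100% of those changed 2-fold, with 11 calls among unchanged genes. For MA against MSC the shares were 64% and 92% with 9 such calls, and for DED against MSC 62% and 86% with 13. The 3 simulations had the same gene means, spread and numbers of arrays, so their shares differ only by the random draw. In the data 25.9% to 33.4% of genes passed, so the adjustment was stricter in the simulations. All genes changed 4-fold or 8-fold were recovered in the 3 simulations. Unnamed transcript probe sets were left out of the gene counts because no symbol was held for them.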

Results

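ASC52 is a human mesenchymal stem cell line from adipose tissue, immortalised with telomerase reverse transcriptase. Undifferentiated cells (MSC) were compared with cells taken through adipogenic differentiation, begun 3 days after seeding and lasting 14 days, and then kept for 7 days either in control medium, RPMI with 10% fetal bovine serum (MA), or in medium conditioned by MDA-MB-231, a human breast carcinoma line (DED). The submitters call the last step dedifferentiation. The medium and the time of harvest of the MSC cells, and whether the conditioned medium was diluted or renewed, are not given in the sources used here. Each group had 5 arrays. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

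Within groups the lowest correlation between arrays over genes was 0.992 in MSC, 0.992 in MA and 0.982 in DED, the last between DED arrays 1 and 3. The first principal component held 56.7% of the variance and set MSC apart, and the second held 23.1% and set DED apart from MA.

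**Figure D1:**
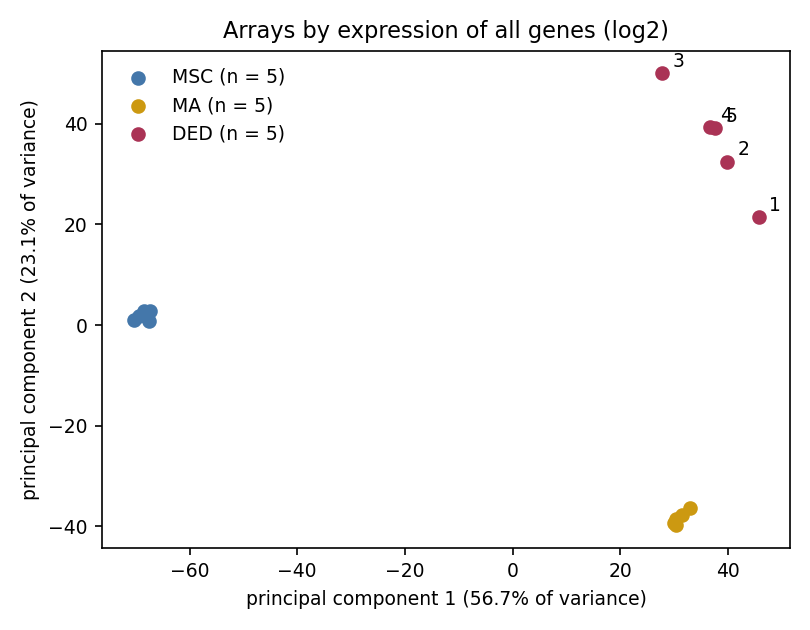
Each point is 1 array, placed by its first and second principal component over the log2 values of all genes, with 5 arrays per group and replicate numbers beside the DED arrays. The groups lie apart along components that hold 56.7% and 23.1% of the variance, and DED arrays 1 and 3 lie at opposite ends of their group.

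The comparison of MA with MSC addressed the differentiation step, and differences in medium or culture time cannot be set apart from it. Many transcripts of fat cells rose. ADIPOQ, which encodes the hormone adiponectin, was 15.15 ± 0.08 in MA (log2 intensity, mean ± SD, n = 5) against 3.91 ± 0.36 in MSC, and FABP4, a fatty acid carrier, was 15.48 ± 0.13 against 4.26 ± 0.33. POSTN, the matrix protein periostin, fell from 16.69 ± 0.06 in MSC to 9.36 ± 0.13 in MA, and MKI67, a marker of dividing cells, fell from 11.61 ± 0.11 to 9.32 ± 0.32. PPARG, the nuclear receptor that drives fat cell formation, rose from 7.06 ± 0.19 to 10.61 ± 0.14, a log2 difference of 3.55 (SE 0.12, limma adjusted p = 1.2e-14).

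The other largest rises were those of CIDEC, a lipid droplet protein, by 9.89 (SE 0.30), the complement component C7 by 9.15 (SE 0.36) and CLEC3B (tetranectin) by 9.01 (SE 0.36). They were followed by PRXL2A, which rose by 8.91 (SE 0.34), THRSP by 8.43 (SE 0.28), the apolipoprotein APOC1 by 8.15 (SE 0.33), the glycerol-3-phosphate dehydrogenase GPD1 by 8.14 (SE 0.33) and the retinol carrier RBP4 by 7.88 (SE 0.24). The largest falls were those of the costimulatory receptor TNFRSF9, which fell by 7.73 (SE 0.44), POSTN (-7.33, SE 0.16), the cholesterol 25-hydroxylase CH25H (-7.32, SE 0.19) and the growth factor NRG1 (-6.08, SE 0.19). Next came the matrix protein TGFBI (-5.46, SE 0.21), the R-spondin receptor LGR4 (-5.40, SE 0.20), the potassium channel KCNMA1 (-5.30, SE 0.38), the metalloprotease ADAM12 (-5.25, SE 0.15), RAB3B (-5.18, SE 0.21) and the hyaluronan-binding protein TNFAIP6 (-5.08, SE 0.21). Adjusted p-values of these 20 genes ran from 1.9e-18 to 6.3e-10. ADIPOQ, FABP4, C7, THRSP and GPD1 lay under the median of the negative control probe sets (4.80) in MSC, as did PLIN1, LEP, FOXO1 and PDE3B. The lower group of all 10 rises and of TNFRSF9, CH25H, NRG1, LGR4, KCNMA1 and RAB3B lay under the 95th percentile of those probe sets (8.31), so the size and order of these differences depend on background.

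Of 22 measured adipocyte markers 19 rose and 3 did not pass the test (19 rose and 1 fell adjusted over the list alone), with a median log2 difference of 5.15 (camera adjusted p = 2.5e-22). PLIN1, which coats lipid droplets, rose by 7.46 (SE 0.34), LPL, lipoprotein lipase, by 2.56 (SE 0.14) and LEP, the hormone leptin, by 1.97 (SE 0.27). All 17 fatty acid and triglyceride synthesis genes rose (17 adjusted over the list alone, median 2.31, adjusted p = 7.8e-21), among them ACACB, an acetyl-CoA carboxylase, by 7.63 (SE 0.22). Of 21 lipolysis and fatty acid oxidation genes 15 rose and 1 fell (the same counts adjusted over the list alone, median 0.97, adjusted p = 1.4e-09), with PDK4 at 4.83 (SE 0.28) and the hormone-sensitive lipase LIPE at 4.03 (SE 0.26). Of 17 adipogenic transcription factors 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 1.19, adjusted p = 1.0e-09), ZBTB16 most, by 7.77 (SE 0.12), and CEBPA by 0.67 (SE 0.13). Insulin signalling genes rose in 11 of 15 cases and fell in 2 (12 and 2 adjusted over the list alone, median 1.37, adjusted p = 1.5e-07), led by FOXO1 at 6.90 (SE 0.25) and the phosphodiesterase PDE3B at 5.73 (SE 0.19). Of 15 glucocorticoid response genes 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 2.47, adjusted p = 1.3e-13), with the monoamine oxidase MAOA at 6.53 (SE 0.13). Of 16 cholesterol synthesis and uptake genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0020, and 0.048 with an estimated correlation), MVD by 3.20 (SE 0.16) and IDI1 by 2.93 (SE 0.14), both enzymes of the mevalonate pathway.

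Cell cycle genes fell in 28 of 30 cases (28 adjusted over the list alone, median -1.63, adjusted p = 8.3e-20), with the mitotic regulators FOXM1 at -2.93 (SE 0.17) and PLK1 at -2.82 (SE 0.17). Of 16 mesenchymal stem cell markers 9 fell and 2 rose (the same counts adjusted over the list alone, median -1.01, adjusted p = 0.00074, and 0.0498 with an estimated correlation). PI16 fell by 4.02 (SE 0.18) and DPP4 by 2.42 (SE 0.28). THY1 was at -1.55 (SE 0.14) and ENG at -1.18 (SE 0.11), while NT5E was 13.83 ± 0.16 in MA and 13.92 ± 0.16 in MSC (adjusted p = 0.64). TGF-beta target genes and mesenchymal transition factors fell in 11 of 20 cases and rose in 4 (11 and 5 adjusted over the list alone, median -0.70, adjusted p = 0.0018), with BHLHE40 at -3.73 (SE 0.13) and INHBA, the activin A subunit, at -3.61 (SE 0.28).

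Another 6 lists passed the preset test and lost the call with an estimated correlation. Of 19 unfolded protein and ATF4 response genes 17 fell (17 adjusted over the list alone, median -1.35; adjusted p = 0.10 with an estimated correlation). CHAC1 was at -2.93 (SE 0.39) and ASNS, asparagine synthetase, at -2.86 (SE 0.16). The estimated correlation takes in the spread within DED, which is outside this comparison. The mean of this list ran from 11.03 to 12.14 in DED, 11.47 to 11.64 in MSC and 10.12 to 10.27 in MA. Of 26 extracellular matrix and fibroblast genes 12 fell and 5 rose (13 and 5 adjusted over the list alone, median -0.28; adjusted p = 0.19 with an estimated correlation). BGN, biglycan, fell by 3.88 (SE 0.16), the collagen COL1A1 by 2.10 (SE 0.12) and FAP by 1.21 (SE 0.17). FN1, fibronectin, fell by 0.24 (SE 0.08, adjusted p = 0.034), and its groups did not overlap (16.43 to 16.52 in MA, 16.71 to 16.74 in MSC). The moderated SE also draws on the spread of other genes. The adjusted p of FN1 was between 0.053 and 0.065 without any 1 of 7 arrays, namely MSC arrays 1 to 5 and MA arrays 3 and 5. It was 0.069 with the replicate number as a block. Of 22 interferon-stimulated genes 12 fell and 1 rose (12 and 2 adjusted over the list alone, median -0.43; adjusted p = 0.12 with an estimated correlation), XAF1 by 1.79 (SE 0.15). Of 23 oxidative phosphorylation genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.25; adjusted p = 0.27 with an estimated correlation), UQCRC2 by 1.09 (SE 0.12). Hypoxia response genes rose in 8 of 17 cases and fell in 3 (8 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.031; adjusted p = 0.27 with an estimated correlation), with ADM, adrenomedullin, at 5.04 (SE 0.14) and VEGFA at -1.18 (SE 0.18). Notch pathway genes rose in 5 of 16 cases (5 adjusted over the list alone, median 0.081, adjusted p = 0.046; adjusted p = 0.085 with an estimated correlation), JAG1 by 1.37 (SE 0.14). The hypoxia call was also lost without MSC array 3 (adjusted p = 0.0502) or MA array 5 (0.0512), and the Notch call without MSC arrays 1 or 2, MA arrays 1 or 2, or DED array 3 (0.051 to 0.069).

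Among the lists that did not pass, 26 inflammatory cytokines and NF-kappaB targets held 6 rises and 5 falls (6 and 6 adjusted over the list alone), with SAA1, an acute phase protein, up by 7.68 (SE 0.21). CXCL8 rose by 0.49 (SE 0.18, adjusted p = 0.040), and its adjusted p was between 0.054 and 0.10 without any 1 of 8 arrays, namely MSC arrays 1, 3, 4 and 5 and MA arrays 1 to 4. IL6 was at 4.89 ± 0.22 in MA and 5.28 ± 0.33 in MSC (adjusted p = 0.054; 0.0052 without MSC array 1, 0.023 without MA array 4, 0.041 with quantile normalization and 0.045 with the replicate number as a block). Of 22 matrix proteases and inhibitors 6 rose and 10 fell (7 and 12 adjusted over the list alone). The collagenase MMP1 fell by 2.70 (SE 0.19), and the stromelysin MMP3 fell from 8.37 ± 0.59 to 6.37 ± 0.20. Of 19 contractile and myofibroblast genes 7 rose and 6 fell (7 and 7 adjusted over the list alone), and ACTA2, smooth muscle actin, was 12.04 ± 0.06 in MA and 12.15 ± 0.28 in MSC (adjusted p = 0.87). Of 14 thermogenic genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), and UCP1 stayed near background at 3.94 ± 0.34 and 3.99 ± 0.09 (adjusted p = 0.84). RUNX2, an osteoblast factor, fell from 12.31 ± 0.21 to 9.81 ± 0.42 among 12 osteoblast markers of which 3 rose and 1 fell (3 and 1 adjusted over the list alone).

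Of the 17687 genes 2724 rose and 3120 fell in MA, 897 and 915 of them by 2-fold or more. In 4776 genes (27.0%) the groups of arrays did not overlap, where chance gives 0.794%. Of the 16 lists past the preset test, 10 kept the call with an estimated correlation (adjusted p from 0.00051 to 0.0498).

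**Figure D2:**
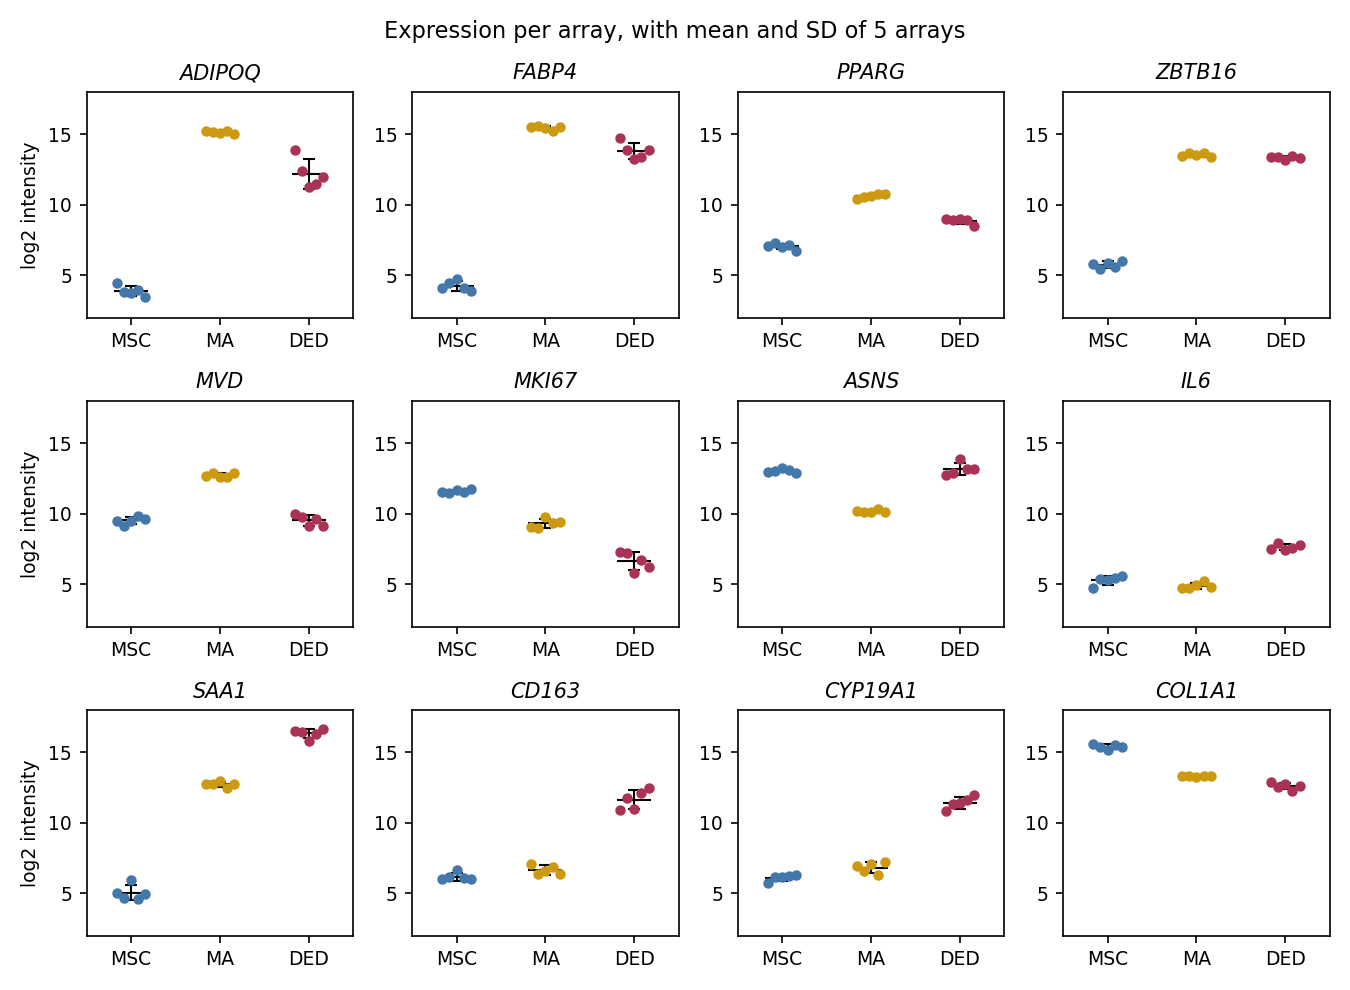
Each point is the log2 intensity of 1 array, with the mean and SD of 5 arrays per group, for 12 genes in MSC, MA and DED. ADIPOQ, FABP4 and PPARG were highest in MA, ASNS was lowest there, MKI67 was lowest in DED, and IL6, SAA1, CD163 and CYP19A1 were highest in DED, where the ADIPOQ values spread most.

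The comparison of DED with MA, the main one of the study, set conditioned against control medium after the same differentiation. Most fat cell transcripts fell, with ADIPOQ at 12.19 ± 1.04 in DED against 15.15 ± 0.08 in MA (log2 intensity, mean ± SD, n = 5) and PPARG at 8.89 ± 0.21 against 10.61 ± 0.14. CEMIP, which degrades hyaluronan, rose from 5.51 ± 0.32 to 11.75 ± 0.42, and CYP19A1, the aromatase that makes estrogens, rose from 6.81 ± 0.39 to 11.42 ± 0.41. The cytokine IL6 rose from 4.89 ± 0.22 to 7.65 ± 0.20, and the amino acid synthesis enzyme ASNS from 10.19 ± 0.09 to 13.17 ± 0.45. MKI67 fell further, from 9.32 ± 0.32 to 6.67 ± 0.64.

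After CEMIP (6.24, SE 0.18) the largest estimated rises were those of the interleukin-33 receptor IL1RL1 by 5.28 (SE 0.15), the metalloreductases STEAP4 by 5.14 (SE 0.44) and STEAP2 by 4.89 (SE 0.17), TNFAIP6 by 5.11 (SE 0.21) and the haptoglobin-hemoglobin receptor CD163 by 4.99 (SE 0.25). They were followed by the BMP antagonist GREM1, which rose by 4.68 (SE 0.28), CYP19A1 by 4.61 (SE 0.19), TNFRSF11B (osteoprotegerin) by 4.49 (SE 0.21) and PAPPA2, a protease of IGF-binding proteins, by 4.04 (SE 0.28). The largest falls were those of CLEC3B (-7.15, SE 0.36), the histone gene H2BC14 (-6.28, SE 0.24), the IGF-binding protein IGFBP6 (-5.31, SE 0.11), SCUBE3 (-4.98, SE 0.14) and lactoferrin LTF (-4.89, SE 0.22). Next came APOC1 (-4.35, SE 0.33), the matrix Gla protein MGP (-4.26, SE 0.38), RBP4 (-4.16, SE 0.24), the prostaglandin-degrading enzyme HPGD (-4.05, SE 0.18) and the mitotic spindle gene DLGAP5 (-3.92, SE 0.21). Adjusted p-values of these 20 genes ran from 2.1e-17 to 4.6e-08. STEAP4 varied within DED, from 8.32 in array 3 to 12.01 in array 1, against 5.35 to 5.72 in MA. DLGAP5 lay under the negative control median in DED. Only IL1RL1, STEAP2, TNFAIP6, APOC1, MGP and RBP4 had both groups above the 95th percentile of the negative controls (8.31), so the size and order of the other differences, that of CEMIP included, depend on background.

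Of 22 adipocyte markers 18 fell and 1 rose (18 and 2 adjusted over the list alone, median -2.08, adjusted p = 1.4e-14, and 0.040 with an estimated correlation). CFD, the complement factor adipsin, fell by 3.75 (SE 0.26), PLIN1 by 2.75 (SE 0.34), FABP4 by 1.64 (SE 0.21) and LPL by 1.61 (SE 0.14). LEP was 7.40 ± 0.85 in DED and 6.73 ± 0.20 in MA (adjusted p = 0.078; 0.026 and 0.044 without DED array 2 or 4). It was at 8.83 in DED array 3, at 6.69 to 7.36 in the other DED arrays and at 6.51 to 7.00 in MA. DED array 1 stood apart in the adipocyte markers, with a list mean of 9.86 against 8.68 to 8.98 in the other DED arrays. Of 17 fatty acid and triglyceride synthesis genes 14 fell (15 adjusted over the list alone, median -0.91; adjusted p = 0.056 with an estimated correlation), ACSS2, an acetyl-CoA synthetase, by 3.50 (SE 0.17), and here too DED array 1 was higher (12.0 against 11.2 to 11.4). Of 21 lipolysis and fatty acid oxidation genes 14 fell and 1 rose (14 and 1 adjusted over the list alone, median -1.04, adjusted p = 1.0e-09), with PDK4 at -2.68 (SE 0.28) and the monoglyceride lipase MGLL at -2.34 (SE 0.15). Of 17 adipogenic transcription factors 8 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.30; adjusted p = 0.11 with an estimated correlation), with PPARG at -1.73 (SE 0.12), CEBPA at -0.54 (SE 0.13) and KLF5 at 1.54 (SE 0.17).

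Cholesterol synthesis and uptake genes fell in 12 of 16 cases and rose in 1 (12 and 2 adjusted over the list alone, median -0.81, adjusted p = 4.7e-09), with MVD at -3.18 (SE 0.16) and EBP at -2.62 (SE 0.15). Of 23 oxidative phosphorylation genes 16 fell (17 adjusted over the list alone, median -0.48, adjusted p = 1.1e-08, and 0.048 with an estimated correlation), the ATP synthase subunit ATP5F1A and the succinate dehydrogenase subunit SDHA each by 0.99 (SE 0.12). Of 18 glycolysis genes 7 fell (8 fell and 2 rose adjusted over the list alone, median -0.36; adjusted p = 0.29 with an estimated correlation), with ALDOC at -1.43 (SE 0.12). DED array 3 lay within the MA range in this list, with a mean of 10.80 against 10.75 to 10.92 in MA and 10.36 to 10.58 in the other DED arrays. Cell cycle genes fell in 29 of 30 cases (30 adjusted over the list alone, median -1.23, adjusted p = 7.3e-27), with MKI67 at -2.65 (SE 0.22), PLK1 at -3.09 (SE 0.17) and the mitotic kinesin KIF20A at -3.84 (SE 0.21).

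Of 26 inflammatory cytokines and NF-kappaB targets 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.34, adjusted p = 1.5e-06). IL6 rose by 2.76 (SE 0.15), CCL2, a monocyte-attracting chemokine, by 2.55 (SE 0.16), CXCL8 by 0.97 (SE 0.18) and SAA1 by 3.62 (SE 0.21), the last to 16.35 ± 0.33. All group means of IL6, CXCL8 and CEBPA lay under the 95th percentile of the negative controls (8.31). The same held for KLF5, LEP, PDPN, IFIT1, CD14, JAG1, XAF1 and JUNB. TGF-beta target genes and mesenchymal transition factors rose in 8 of 20 cases and fell in 1 (8 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.015, and 0.048 with an estimated correlation), the receptor TGFBR1 by 2.25 (SE 0.13) and SKIL by 1.84 (SE 0.16). Unfolded protein and ATF4 response genes rose in 15 of 19 cases and fell in 1 (16 and 1 adjusted over the list alone, median 1.56; adjusted p = 0.082 with an estimated correlation), CHAC1 by 3.29 (SE 0.39) and ASNS by 2.98 (SE 0.16). Their mean was higher in DED array 3 than in DED array 1 by 1.11, and CHAC1 had an SD of 1.23 in DED.

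The extracellular matrix list moved both ways, with 7 rises and 10 falls among 26 genes (9 and 12 adjusted over the list alone, adjusted p = 0.42). FN1 rose by 0.44 (SE 0.08) and PDPN, podoplanin, rose by 2.19 (SE 0.18), while the calcium-binding protein S100A4 fell by 3.15 (SE 0.17), COL1A1 by 0.69 (SE 0.12) and FAP by 0.62 (SE 0.17). Of 19 contractile and myofibroblast genes 10 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.058). CCN1 rose by 1.47 (SE 0.16), TGFBI fell by 3.41 (SE 0.21) and ACTA2 was 12.62 ± 1.17 in DED and 12.04 ± 0.06 in MA (adjusted p = 0.28). DED array 3 stood apart in this list, with a mean of 11.4 against 10.6 to 10.8, and the list passed without MSC array 2 or any 1 of DED arrays 1, 2, 4 and 5 (adjusted p from 0.033 to 0.049). Mesenchymal stem cell markers held 4 rises and 4 falls among 16 (4 and 5 adjusted over the list alone, adjusted p = 0.82), with THY1 at 0.76 (SE 0.14), ENG at 0.74 (SE 0.11) and NT5E at -0.70 (SE 0.12).

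Other lists did not pass in DED against MA, and their counts adjusted over the list alone stand second. Matrix proteases and inhibitors held 5 rises and 5 falls among 22 (6 and 5), with MMP1 up by 1.11 (SE 0.19) and MMP3 at 6.44 ± 0.35 against 6.37 ± 0.20 (adjusted p = 0.86). Insulin signalling genes held 3 rises and 6 falls among 15 (3 and 6), with the receptor substrate IRS2 up by 2.12 (SE 0.16) and PDE3B down (-2.53, SE 0.19). Secreted growth factors held 9 rises and 5 falls among 25 (9 and 5). Wnt pathway genes held 7 rises and 3 falls among 23 (7 and 3), with the antagonist SFRP4 up by 3.52 (SE 0.26), and osteoblast markers 1 and 1 among 12 (1 and 1), with RUNX2 up by 2.72 (SE 0.18). Hypoxia response genes held 3 rises and 5 falls among 17 (3 and 5), with VEGFA up by 1.59 (SE 0.18), and glucocorticoid response genes 4 and 3 among 15 (4 and 3). Interferon-stimulated genes held 2 rises and 5 falls among 22 (2 and 5), with IFIT1 (-2.24, SE 0.14) and IFI6 (-1.41, SE 0.22) down. Notch pathway genes held 0 rises and 2 falls among 16 (0 and 2) and thermogenic genes 0 and 4 among 14 (0 and 4), with UCP1 at 3.84 ± 0.17 in DED and 3.94 ± 0.34 in MA. Chondrocyte markers held 1 rise and 2 falls among 14 (1 and 2), with lubricin PRG4 down (-3.68, SE 0.20), and autophagy and lysosome genes 4 and 4 among 16 (4 and 6). Of markers of other cell types, 0 of 15 carcinoma epithelial markers passed the test (0 adjusted over the list alone, adjusted p of the list 0.60), and 2 of 13 endothelial markers rose (1). Macrophage and leukocyte markers held 2 rises, CD163 and CD14, and 1 fall, CD68, among 18 (2 and 1).

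Of the 17687 genes 2283 rose and 2304 fell, 495 and 616 of them by 2-fold or more. In 3200 genes (18.1%) the groups did not overlap, where chance gives 0.794%. With DED arrays 1 and 3 both left out, 2167 rose and 2107 fell, so that the balance of rises and falls was not fixed. Of the 11 lists past the preset test 7 kept the call with an estimated correlation (adjusted p from 0.00051 to 0.048).

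**Figure D3:**
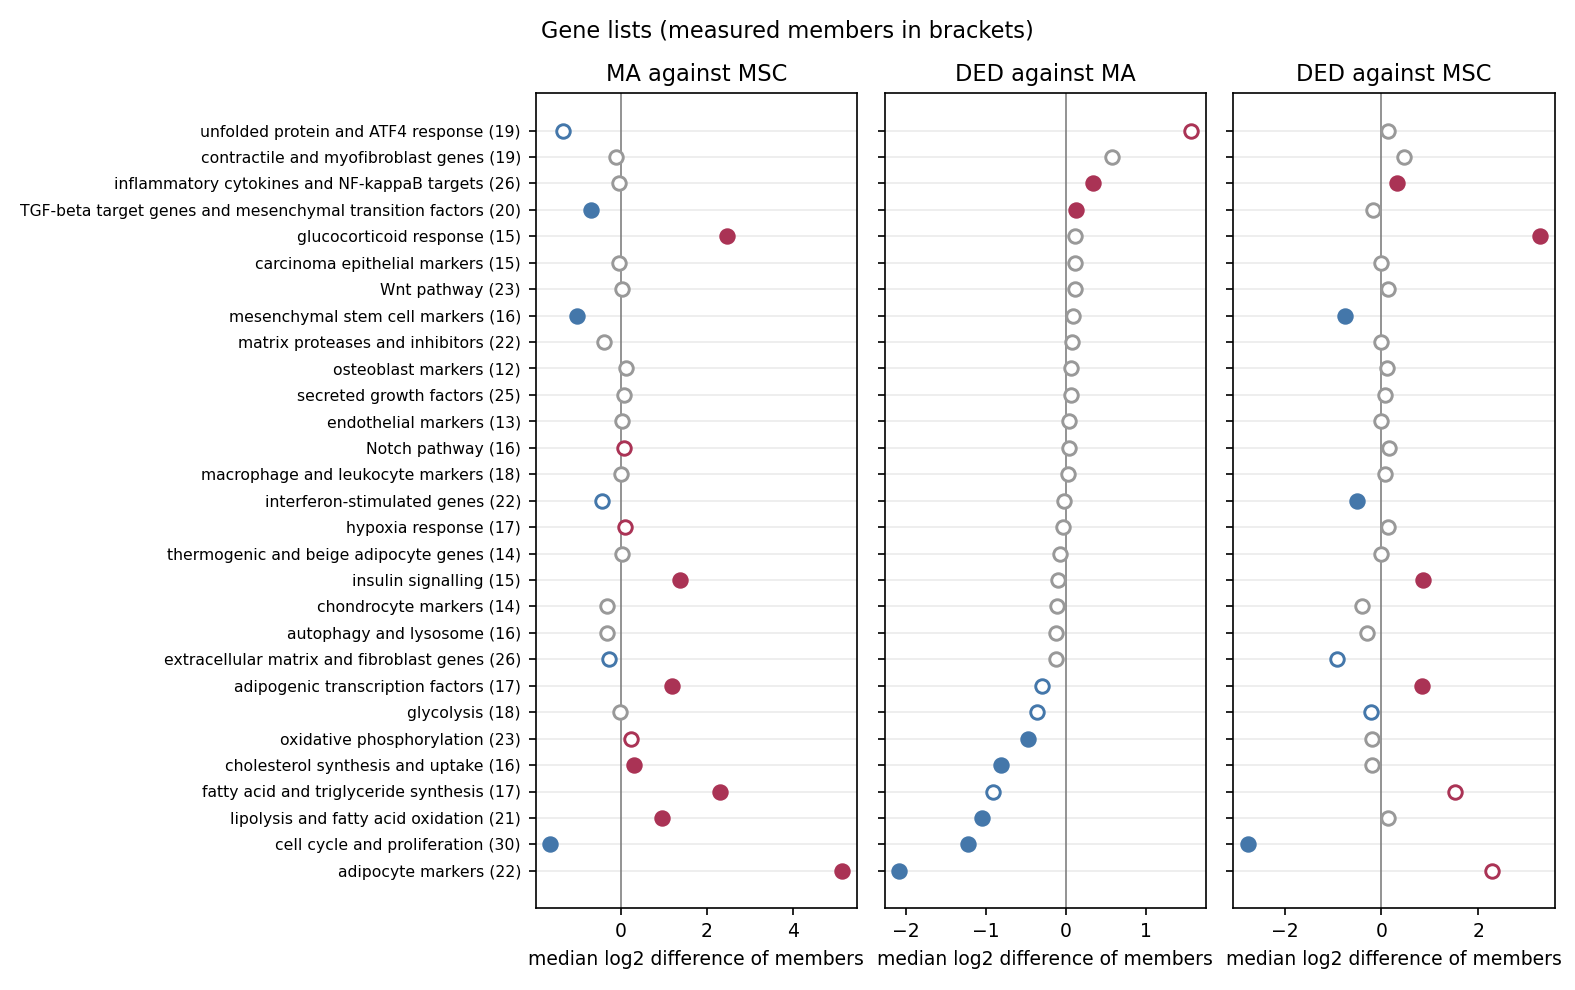
Each point is the median log2 difference of the measured members of a fixed gene list in 1 of the 3 comparisons, red for lists called up and blue for lists called down. Filled points passed the test with the preset and the estimated correlation, hollow coloured points with the preset correlation only, and grey points did not pass; adipocyte markers were at 5.15, -2.08 and 2.28 and cell cycle genes at -1.63, -1.23 and -2.76.

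The comparison of DED with MSC showed how far the cells in conditioned medium stood from undifferentiated ones. SAA1 rose from 5.05 ± 0.54 in MSC to 16.35 ± 0.33 in DED (log2 intensity, mean ± SD, n = 5), and IL1RL1 rose from 5.51 ± 0.11 to 15.57 ± 0.23. FABP4 remained 9.58 above MSC (SE 0.21) and ADIPOQ 8.28 (SE 0.33), while PPARG was 1.82 above (SE 0.12). H2BC14 fell from 14.86 ± 0.13 to 5.98 ± 0.77, and POSTN fell from 16.69 ± 0.06 to 8.71 ± 0.45. MKI67 fell from 11.61 ± 0.11 to 6.67 ± 0.64.

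The remaining largest rises were those of the protease inhibitor A2M by 7.65 (SE 0.19), ZBTB16 by 7.58 (SE 0.12) and the carboxypeptidase CPM by 7.53 (SE 0.14). Next came the secreted glutathione peroxidase GPX3, up by 7.02 (SE 0.38), the cell adhesion molecule NRCAM by 7.02 (SE 0.18) and C7 by 6.94 (SE 0.36). The remaining largest falls were those of TGFBI (-8.87, SE 0.21), TNFRSF9 (-6.64, SE 0.44), IGFBP6 (-6.61, SE 0.11) and KIF20A (-6.60, SE 0.21). They were followed by PRG4 (-6.56, SE 0.20), DLGAP5 (-6.30, SE 0.21), the collagen COL14A1 (-6.12, SE 0.22) and the histone gene H3C2 (-6.04, SE 0.20). TNFRSF9 was 9.01 in DED array 3 and 5.30 to 6.76 in the other DED arrays, and its log2 difference was -7.25 without that array. Adjusted p-values of the 20 genes ran from 4.4e-20 to 2.0e-10. A2M, ADIPOQ, FABP4 and C7 lay under the negative control median in MSC, and KIF20A and DLGAP5 in DED. Only NRCAM and POSTN had both groups above the 95th percentile of the negative controls (8.31), so the size and order of the other differences, those of SAA1 and H2BC14 included, depend on background.

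All 30 cell cycle genes fell (30 adjusted over the list alone, median -2.76, adjusted p = 1.8e-34), PLK1 by 5.91 (SE 0.17). Of 22 adipocyte markers 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 2.28; adjusted p = 0.0505 with an estimated correlation), with PLIN1 at 4.71 (SE 0.34), LEP at 2.64 (SE 0.27) and LPL at 0.95 (SE 0.14). Of 17 fatty acid and triglyceride synthesis genes 14 rose (14 adjusted over the list alone, median 1.51; adjusted p = 0.057 with an estimated correlation), ACACB by 5.49 (SE 0.22). Of 17 adipogenic transcription factors 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.84, adjusted p = 3.1e-06), while CEBPA was 5.43 ± 0.20 in DED and 5.30 ± 0.15 in MSC (adjusted p = 0.53). Glucocorticoid response genes rose in 13 of 15 cases and fell in 1 (13 and 1 adjusted over the list alone, median 3.28, adjusted p = 1.7e-13), MAOA by 5.84 (SE 0.13). Insulin signalling genes rose in 10 of 15 cases and fell in 2 (10 and 2 adjusted over the list alone, median 0.85, adjusted p = 1.1e-05), FOXO1 by 6.84 (SE 0.25). Of 26 inflammatory cytokines and NF-kappaB targets 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.32, adjusted p = 6.6e-05), IL6 by 2.37 (SE 0.15) and CXCL8 by 1.46 (SE 0.18).

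Of 26 extracellular matrix and fibroblast genes 16 fell and 6 rose (17 and 8 adjusted over the list alone, median -0.93; adjusted p = 0.12 with an estimated correlation), with COL1A1 at -2.79 (SE 0.12) and FAP at -1.83 (SE 0.17). FN1 was at 16.93 ± 0.04 in DED and 16.72 ± 0.01 in MSC (adjusted p = 0.072). Its groups did not overlap (16.86 to 16.96 in DED, 16.71 to 16.74 in MSC), and the moderated test also draws on the spread of other genes. Of 16 mesenchymal stem cell markers 10 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.76, adjusted p = 0.00060, and 0.048 with an estimated correlation), among them PI16 (-3.97, SE 0.18). THY1 was at -0.79 (SE 0.14), NT5E at -0.79 (SE 0.12) and ENG at -0.44 (SE 0.11). Of 22 interferon-stimulated genes 10 fell (11 adjusted over the list alone, median -0.50, adjusted p = 0.00022, and 0.040 with an estimated correlation), IFI6 by 2.44 (SE 0.22). Of 18 glycolysis genes 7 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.22; adjusted p = 0.39 with an estimated correlation, and 0.063 without MSC array 2), and DED array 3, with a mean of 10.80, lay within the MSC range of 10.68 to 11.06. MMP1 fell by 1.60 (SE 0.19) and MMP3 by 1.93 (SE 0.22). ACTA2 was 12.62 ± 1.17 and 12.15 ± 0.28 (adjusted p = 0.37), and UCP1 was 3.84 ± 0.17 and 3.99 ± 0.09 (adjusted p = 0.46).

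In this comparison 3022 genes rose and 2892 fell, 878 and 1003 of them by 2-fold or more, and in 4442 genes (25.1%) the groups did not overlap, where chance gives 0.794%. Of the 11 lists past the preset test 7 kept the call with an estimated correlation (adjusted p from 0.00051 to 0.048). The list median, mean and test differed in sign for thermogenic, glycolysis, inflammatory, chondrocyte and endothelial lists in MA against MSC and for the Notch list in DED against MA. They also differed for the contractile, unfolded protein and carcinoma lists in DED against MSC, none of which passed there.

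Genes raised by differentiation fell more often than they rose in conditioned medium, whereas genes lowered by differentiation went both ways. Among genes of the first kind RBP4 fell from 13.80 ± 0.17 in MA to 9.64 ± 0.47 in DED, with 5.92 ± 0.60 in MSC (mean ± SD, n = 5). TNFAIP6 was 13.44 ± 0.14 in MSC, 8.36 ± 0.21 in MA and 13.48 ± 0.62 in DED, and ASNS followed the same course with 13.05 ± 0.12, 10.19 ± 0.09 and 13.17 ± 0.45. TGFBI fell in both steps, from 16.40 ± 0.03 to 10.95 ± 0.14 and 7.53 ± 0.65, and SAA1 rose in both.

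Of 897 genes at least 2-fold higher in MA than in MSC, 535 (59.6%) fell in DED against MA and 123 (13.7%) rose, where independent lists would share 117 and 116. Of the 535 genes 375 still passed as higher in DED than in MSC, 139 did not pass and 21 were lower. Of 915 genes at least 2-fold lower in MA, 313 (34.2%) rose and 284 (31.04%) fell, where independent lists would share 118 and 119; without DED array 3 the counts were 295 and 299. Of the 313 genes 159 were still lower in DED than in MSC, 123 did not pass and 31 were higher. The median log2 difference from MSC of the 897 genes was 1.62 in MA and 1.13 in DED, and that of the 915 genes was -1.47 and -1.50.

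The MA arrays enter both comparisons with opposite sign. Over genes, which are not independent replicates, the log2 differences correlated at -0.29 with a covariance of -0.135, and 100 simulations of unchanged groups gave a mean correlation of -0.50 and a mean covariance of -0.0125. With the MA arrays split into 2 and 3 in all 20 ways, so that the comparisons shared none, 436 to 505 genes rose and then fell and 88 to 126 rose in both steps. In the same splits 238 to 286 genes fell and then rose and 213 to 270 fell in both steps.

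**Figure D4:**
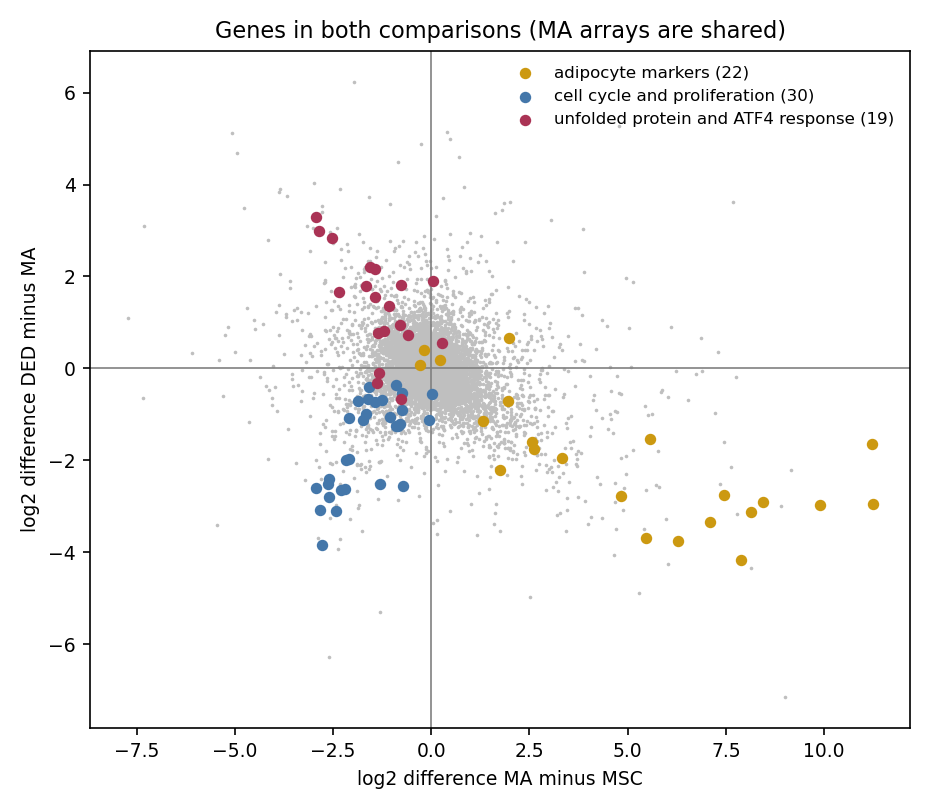
Each point is 1 gene, with its log2 difference MA minus MSC across and DED minus MA upwards, and members of 3 fixed lists in colour. Most adipocyte markers lie at the lower right, cell cycle genes at the lower left and unfolded protein and ATF4 response genes at the upper left, and the MA arrays are shared by both axes.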

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

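Of the tests below, those of the extent of the response in DED arrays 1 and 3 and of genes at the same level as the cell cycle genes were chosen only after the result was seen.

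The largest gap between the highest or lowest array and its neighbour, as a share of the group's range, was computed for 447 groups of 5 arrays, 360 of genes named in the text and 87 of list means. It passed Dixon's 95% value in 31 and 5 groups, and chance flags about 1 in 20 groups. In DED, array 1 was far from the others in PDE3B (gap ratio 0.831), PDK4 (0.815), APOC1 (0.764), GPD1 (0.752), THY1 (0.718), CIDEC (0.715), PLIN1 (0.715) and CEBPA (0.712) and in the means of the fatty acid and triglyceride synthesis list (0.803) and the adipocyte marker list (0.745), in each case as the highest array. DED array 3 was the highest in ACTA2 (0.846), TGFBI (0.724), MGLL (0.711) and the mean of the contractile list (0.834). Other DED arrays stood apart in PPARG (0.765) and ENG (0.711), both DED array 5, and in LGR4 (0.75), DED array 2.

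In MSC, array 2 was the lowest in SFRP4 (0.812), PRG4 (0.804), NT5E (0.795), MGLL (0.736), TNFRSF11B (0.733), COL14A1 (0.730) and the mean of the autophagy and lysosome list (0.917), and the highest in the mean of the oxidative phosphorylation list (0.751). Single MSC arrays also stood apart in ALDOC (0.793), TGFBR1 (0.780), CD163 (0.771), ACACB (0.759), TGFBI (0.75) and CYP19A1 (0.722). In MA this held for MMP3 (0.857), IL1RL1 (0.810), CPM (0.739), ALDOC (0.727) and NRCAM (0.718).

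Transcript probe sets without a gene symbol were outside the gene counts. Of 3739 such probe sets 817 passed the test in MA against MSC, 591 in DED against MA and 844 in DED against MSC, against 4, 0 and 3 of 612 negative controls. Each set was adjusted over itself alone, so the control counts give no rate of false calls for the unnamed probe sets. No explanation was tested for them.

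The counts of changed genes were set against 100 splits of each comparison's 10 arrays into 5 and 5. In each comparison 1 split, the real one, gave as many genes, so a random grouping of these arrays did not give such counts. The other splits mix the groups, and the arrays may not be separate cultures. The splits therefore cannot exclude chance differences between cultures. The real splits gave 5844, 4587 and 5914 genes and the highest other splits 4, 874 and 367.

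Cell cycle genes were lower in DED than in MA, with a list median of -1.23 and no overlap between the groups in 25 of 30 genes. A shift of all genes of that brightness is argued against by 1409 genes outside the cell cycle lists with the nearest mean levels, whose median was 0.012 (quartiles -0.23 and 0.28). Quantile normalization left the list median at -1.25, but that setting moved the log2 differences by a median of only 0.0171, so it decides nothing about the normalization. Fewer undifferentiated cells in DED could lower cell cycle genes, and would also lower other genes that MSC express more than MA. The rule set beforehand took a median that was not negative as against this, and the median of 882 such genes was 0.094. But 313 of them rose and 251 fell, with quartiles of -0.55 and 0.78. A requirement on the quartiles, which was not part of that rule, was applied, and with it the median cannot exclude fewer undifferentiated cells. This explanation cannot be told apart from an effect of the conditioned medium on dividing cells, which stays open and untested.

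CD163 rose by 4.99 in DED against MA and CD14, another receptor of macrophages, by 1.4, while CD68 fell by 1.18. All group means of CD14 lay under the 95th percentile of the negative controls (8.31). Macrophages among the DED cells would bring their other abundant transcripts, but of TYROBP, FCER1G, AIF1, LAPTM5 and C1QB, a set written before these values were seen, 0 rose, and their median log2 difference was -0.034 (from -0.17 to 0.22). All but TYROBP lay near the negative control median in both groups, at 4.55 to 5.14. These values argue against macrophages as the source. A response of the cultured cells themselves, differentiated or not, to conditioned medium, which the design gives, may remain as a hypothesis. It was found on these data and was not tested.

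DED arrays 1 and 3 lay at opposite ends of their group. A different extent of the response to conditioned medium could part them: across genes DED 3 minus DED 1 correlated at 0.292 with the difference of DED arrays 2, 4 and 5 from MA, just under the 0.3 set for that case, and of 1146 genes at least 2-fold changed in those 3 arrays 71.6% had the same sign. Placed between MA at 0 and the mean of DED arrays 2, 4 and 5 at 1, DED array 1 lay at 0.780 and DED array 3 at 1.06. Array brightness gave a correlation of 0.128 with the genes' mean level, between the 2 bounds set. List means went both ways. DED 3 minus DED 1 had the sign of DED arrays 2, 4 and 5 minus MA in adipocyte markers (-1.18 and -2.14). The sign was also the same in unfolded protein and ATF4 response genes (1.11 and 1.37). It was opposite in glycolysis genes (0.39 and -0.36) and Wnt pathway genes (-0.15 and 0.35), which are fixed lists too. It was also opposite in iron and metal handling genes (-0.75 and 1.399) and acute phase and STAT3 response genes (-0.34 and 0.84). The iron and acute phase lists were written after the largest changes were seen. A different extent alone would not give opposite signs, but DED 3 minus DED 1 rests on 1 array per side. Neither test decides, so both explanations cannot be told apart for these arrays. Neither was shown to account for the whole gap.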

How the results depend on the processing

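Leaving out DED arrays 1 and 3 together, and leaving out each array in turn for the lists, were chosen after seeing the data; the other alternatives were planned. All counts of changed and overlapping genes stayed within 1.5 times their values under every alternative, but close balances of rises and falls turned. In DED against MA (2283 and 2304) they became 2511 and 2422 with array weights, 2351 and 2333 with dim genes left out, 2654 and 2534 with all probe sets and 2167 and 2107 without DED arrays 1 and 3, and turned without DED array 1, MA array 4 or MA array 5. At 2-fold or more in MA against MSC (897 and 915) they became 923 and 883 with quantile normalization and 912 and 899 with arrays shifted to 1 median, and were equal without MA array 2. Among genes lowered in MA, rises and falls in DED (313 and 284) became 295 and 299 without DED array 3. With 1 array left out, the rises in DED against MA ran from 2017 to 2471 and the falls from 2100 to 2305. Lists past the test fell from 16, 11 and 11 (MA against MSC, DED against MA, DED against MSC) to 10, 7 and 7 with an estimated correlation, the only alternative that ended 11 of the 14 calls it ended. With fry, which compares a list with no other genes, they numbered 23, 22 and 25. The Notch list in MA against MSC (adjusted p = 0.046) also lost its call with quantile normalization (0.061), the replicate block (0.053), the 2 groups alone (0.057) and DED arrays 1 and 3 out (0.054), and the hypoxia list (0.031) with the last pair (0.054 and 0.054). The contractile list in DED against MA gained one with quantile normalization (0.041) and the 2 groups alone (0.049), and the cholesterol list in DED against MSC without DED array 1 (0.047) or arrays 1 and 3 (0.045). The cause was not tested.

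The replicate numbers did not pair the arrays: deviations of arrays with the same number correlated between -0.048 and 0.087 (MA and MSC), -0.030 and 0.049 (DED and MA) and -0.11 and 0.0056 (DED and MSC), and 1, 0 and 0 of 5 arrays fitted their own number best. With the replicate block 2653 genes rose and 3010 fell in MA against MSC, 2206 and 2234 in DED against MA, and 2927 and 2811 in DED against MSC.

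Of 380 results for single genes 363 passed the test. Most named genes were chosen because they had passed, so these shares do not describe all genes. The call was lost by 16 with 1 array left out, FN1 and CXCL8 in MA against MSC among them, and by 9 under another alternative. These counts overlap, and FN1 in MA against MSC is in both. Signal over background limits genes such as UCP1, whose group means lay under the negative control median, and folds against such levels.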

Other observations

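The 9 lists below were written after the largest changes had been seen, so their tests are not independent of the data, and all tests here were chosen after the result was seen. Genes of amino acid uptake and synthesis that the transcription factor ATF4 controls fell on differentiation and rose in conditioned medium, for which it is not given in the sources used here whether the medium was renewed. Of 26 such genes 24 fell in MA against MSC (24 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation) and 24 rose in DED against MA (26 adjusted over the list alone, median 1.86, adjusted p = 0.025 with an estimated correlation). SLC7A5, an amino acid transporter, was 12.02 ± 0.16 in MSC, 8.16 ± 0.16 in MA and 11.99 ± 1.05 in DED (mean ± SD, n = 5), the cystine transporter SLC7A11 was 11.85 ± 0.19, 8.19 ± 0.13 and 11.94 ± 0.77, and the secreted protein STC2 rose by 3.07 (SE 0.35) in DED against MA. Endoplasmic reticulum chaperones held 9 rises and 2 falls among 20 in that comparison (11 and 3 adjusted over the list alone, median 0.32; adjusted p = 0.33 with an estimated correlation, and 0.060 with dim genes left out). The ATF4 list mean was higher in DED array 3 than in DED array 1 by 1.41. The chaperone mean was 11.66 in DED array 1, within the MA range of 11.65 to 11.72, and 12.03 to 12.08 in the other DED arrays, so the rise was absent in that array.

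Iron and metal handling genes held 13 rises and 1 fall among 19 in DED against MA (13 and 2 adjusted over the list alone, median 0.68, adjusted p = 0.036 with an estimated correlation). DED array 3 stood apart in this list, with a mean of 10.45 against 11.00 to 11.21 in the other DED arrays and 9.63 to 9.84 in MA. The zinc and iron importer SLC39A14 rose by 2.93 (SE 0.20) and the metallothionein MT1X by 1.71 (SE 0.24), while the iron exporter SLC40A1 fell by 1.25 (SE 0.18). Acute phase and STAT3 response genes held 9 rises and 1 fall among 21 (10 and 1 adjusted over the list alone, median 0.27, adjusted p = 0.017 with an estimated correlation), with JUNB up by 2.42 (SE 0.14) and the receptor LIFR down (-2.25, SE 0.14). G2 and M phase genes fell in 25 of 26 cases (25 adjusted over the list alone, median -1.99, adjusted p = 0.00042 with an estimated correlation) and G1 and S phase genes in 21 of 25 (22 adjusted over the list alone, median -0.91, adjusted p = 0.00022 with an estimated correlation). Complement genes held 1 rise and 5 falls among 13 (2 and 5 adjusted over the list alone, adjusted p = 0.15), NRF2 targets 4 and 6 among 15 (4 and 6 adjusted over the list alone, adjusted p = 0.47, with a median of -0.018 and a mean of 0.078), and 2 of 17 ribosomal protein genes fell (0 adjusted over the list alone, adjusted p = 0.13). The mean of the NRF2 list was 10.43 in DED array 3, 9.60 to 9.90 in the other DED arrays and 9.72 to 9.88 in MA.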
